A study of Mus musculus with 96 samples.

How the data were processed

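Messenger RNA was measured in mouse hippocampus and prefrontal cortex after maternal immune activation (MIA) or saline and with the CSF1R inhibitor PLX5622 (PLX) or control, in females and males. The labels give 96 libraries in 16 groups, 48 libraries per tissue, with 6 libraries per group except MIA control females (7) and MIA control males (5) in each tissue. All 96 libraries were used, and groups, tissue and sex were taken from the labels. The labels do not give the agent of immune activation, the dose or timing of the inhibitor, or the litter of an animal. The labels name each library as a separate sample, so the p-values measure the spread between libraries within a group. Immune activation was maternal, and animals of a shared litter would not be independent replicates of it. Litter could not be modelled, so every p-value for an MIA effect or its interaction takes the libraries of a group as independent. Such p-values may be too small, and they cannot part an effect of MIA from differences between litters.

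The submitters' processing notes name Trimmomatic for trimming and STAR 2.6.1d for alignment to GRCm39 (mm39). The tool that counted reads per gene is not given in the sources used here. The deposited table holds 22709 genes by symbol in 96 columns, and its deposited values are a signal, namely counts divided by a factor for each library. In 75 columns every value was a whole number after multiplication by the recovered factor (tolerance 0.01). In the other 21 columns the factor lay within 1% of 1, so whole numbers there could not be told from chance; these columns were used in the same way. The factors ran from 0.898 to 1.112 in hippocampus and 0.931 to 1.107 in prefrontal cortex. The median ratio of a library to its tissue's reference deviated from 1 by at most 0.0380% in hippocampus and 0.0500% in prefrontal cortex, against 0.835% over all 96 libraries, so the scaling was done within each tissue. Recovered reads per library ran from 22.2 M to 26.7 M in hippocampus and from 22.8 M to 25.9 M in prefrontal cortex. No gene encoded on the mitochondrial genome is in the table. Over all libraries the lowest total of a gene was 127 reads, the number of identical library columns was 0, and the highest correlation between a pair of libraries was 0.990. Genes are identified by symbol in the table, without coordinates.

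Each tissue was fitted on its own with limma 3.58.1 in R 4.3.3. Values were log2(signal + 1), all 8 groups of the tissue were in one linear model, and variances were moderated with a trend on mean level. Genes with a signal of at least 10 in at least 5 libraries were tested (19938 in hippocampus, 19841 in prefrontal cortex). Tests were two-sided with Benjamini-Hochberg adjustment within each comparison, and a gene was called at an adjusted p under 0.05. Counts at an unadjusted p under 0.05 are given beside the calls. Chance alone would put a share of about 0.05 of the tested genes there, so such counts are no signal by themselves. Per tissue the comparisons were MIA against saline and PLX against control within each sex and level of the other factor, the MIA by PLX interaction in each sex, and the difference between sexes of the MIA effect without inhibitor, the PLX effect and the interaction. The tissue difference of the MIA and PLX effects was tested in each sex, in 1 fit of all 16 groups. That fit takes the 2 libraries of an animal label as independent, and an alternative used the label as a block (consensus correlation 0.395). The comparisons, their tests, the gene lists and most alternatives were fixed before the data were examined. The averages of PLX against control, of MIA against saline and of females against males over the other factors were chosen after seeing the data, as were 2 alternatives named below.

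Genes named in the report follow a fixed rule. With at least 20 calls these are the 10 smallest p-values in each direction, with 1 to 19 calls every gene, and with 0 calls the 5 smallest p-values; interaction, sex and tissue terms name 3 genes when nothing was called. Predicted genes were counted, and were named only where fewer than 5 others were available. Csf1r, P2ry12, Tmem119 and Cx3cr1 are given in each inhibitor comparison whatever their result, and Xist and Ddx3y serve as sex checks. Some genes that the rule would name are not reported here. In the averaged comparisons the genes are ordered by the fit that carries a term for the libraries that stand apart.

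Gene lists of cell types and processes were written by hand (39 lists, 789 symbols, of which 743 are in the table), and lists with at least 4 tested members were tested (36 in hippocampus, 37 in prefrontal cortex). Lists were tested with camera in limma at its preset correlation of 0.01, adjusted over the lists of one comparison. The same test with the correlation between members estimated from the data is given beside it, since it is far stricter for lists whose members move together. Counts adjusted over the list alone use the gene p-values of the members with Benjamini-Hochberg within the list. Single values (Csf1r, and the mean of the microglia and immediate early lists) were also compared with exact permutation tests of the group labels, adjusted over families of 8.

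In each tissue the libraries were ordered on the first principal component of the centred log2 values and parted at the largest gap. The 14 libraries on one side are called the libraries that stand apart. They were found in the data and are no group of the design. The share of a library's reads on ribosomal protein genes and nuclear genes of oxidative phosphorylation is given for them as a percentage.

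The alternatives were a pseudocount of 0.5 or 5, no filter, a mean signal of at least 100, equal library totals, edgeR 4.0.16 (quasi-likelihood, TMM) and DESeq2 1.42.0 on the recovered reads, array weights, the replicate number as a block, covariates for dissection (means of the choroid plexus, striatal and oligodendrocyte lists), only the compared groups in the fit, each library left out in turn, and an estimated correlation in camera. A term for the libraries that stand apart and a fit without those libraries were chosen after seeing the data. DESeq2 was not run for the differences between tissues. Their effects are given in the closing section.

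The procedure was tested on simulated data for PLX against control in saline males. With 200 changed genes among 19757, hippocampus gave 163 in the right direction and 4 false calls; of 67 genes at 1.5-fold 44 were found, of 67 at 2-fold 54, and of 66 at 4-fold 65. For prefrontal cortex (19682 genes) 158 of 200 were found with 9 false calls, with 42 of 67, 52 of 67 and 64 of 66 at these folds. A simulated shift of -0.3 in the microglia list came back as a median of -0.30 in each tissue. Counts were drawn from a negative binomial with the dispersions estimated from each tissue, without libraries that stand apart, so the simulation bears on independent noise between libraries alone.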

Results

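The series asks how renewing microglia with injections of a CSF1R inhibitor bears on behaviour after maternal immune activation, and whether the answer differs between the sexes. The comparisons here cover the transcriptomes of hippocampus and prefrontal cortex.

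Sex labels matched expression in all 96 libraries. Xist, the RNA that silences an X chromosome in females, had a signal of 10963.5 to 34956 in the 25 female hippocampal libraries and 2.89 to 40.4 in the 23 male ones; in prefrontal cortex the ranges were 9658.5 to 28462 and 0.940 to 29.0. Summed Y-linked transcripts lay between 0 and 5.57 in female libraries and between 3007.1 and 5398.2 in male libraries over both tissues.

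The widest difference between libraries went with genes of protein synthesis and respiration, among others. Ribosomal protein genes and nuclear genes of oxidative phosphorylation took 0.664 ± 0.0329% of reads (mean ± SD) in 14 hippocampal libraries and 0.481 ± 0.0299% in the other 34. In prefrontal cortex the values were 0.650 ± 0.0315% and 0.452 ± 0.0407%, and the same 14 labels stood apart in both tissues. The first principal component, on which these libraries part from the rest, held 25.3% of the variance in hippocampus and 27.9% in prefrontal cortex. Xist in females also parted without overlap. In hippocampus it was 10963.5 to 14318 in the libraries that stand apart and 21284 to 34956 in the rest. In prefrontal cortex it was 9658.5 to 12710 and 18060.5 to 28462. The labels do not tell whether the parting arose in the tissue or in the RNA and libraries. The 14 were 12 of the 24 control and 2 of the 24 PLX labels (Fisher's exact test, two-sided p = 0.00335). By prenatal treatment they were 6 MIA and 8 saline labels (exact p = 0.752), and by sex 6 female and 8 male labels (exact p = 0.529). By group they were 3 of 6 saline control females, 4 of 6 saline control males, 2 of 7 MIA control females, 3 of 5 MIA control males, 1 of 6 MIA PLX females and 1 of 6 saline PLX males. Counts of called genes are therefore given as designed, with a term for these libraries, and without them.

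**Figure D1:**
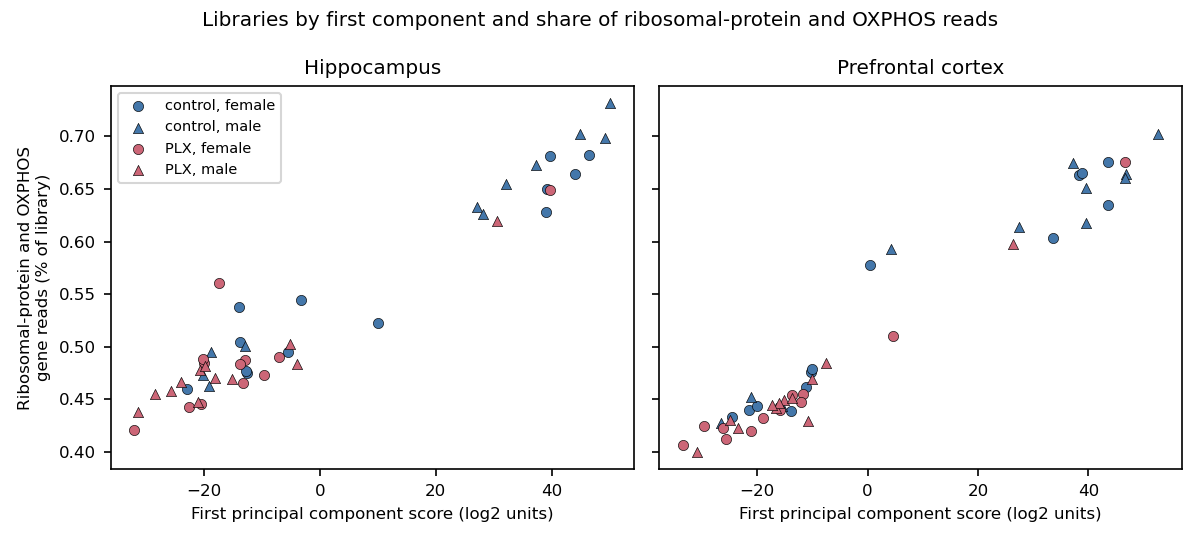
Each point is a library, placed by its score on the first principal component (x axis, log2 units) and the share of its reads on ribosomal protein and oxidative phosphorylation genes (y axis, %), coloured by inhibitor with the marker giving sex. In each tissue 14 libraries lie to the right, with mean shares of 0.664% in hippocampus and 0.650% in prefrontal cortex.

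In saline females given the inhibitor, some hippocampal genes of resting microglia fell. These were Fcrls, an Fc receptor-like scavenger receptor (log2 fold change -0.56 ± 0.10 SE, adjusted p = 0.0383), Gpr34, a lysophospholipid receptor (-0.63 ± 0.12, adjusted p = 0.0383), and the purinergic receptor P2ry12 (-0.42 ± 0.08, adjusted p = 0.0389). Every one of the 6 PLX libraries lay below every control library for Fcrls (386 to 468 against 480 to 785). The unconventional myosin Myo18b (-0.64), the tetraspanin Upk1b (-0.97) and the lectin Cd209a of macrophages and dendritic cells (-2.21) also fell. Of the other receptors of interest, Csf1r itself differed by -0.14 ± 0.07 (adjusted p = 0.201), Tmem119 by -0.24 ± 0.11 (adjusted p = 0.187) and Cx3cr1 by -0.41 ± 0.09 (adjusted p = 0.0764). The microglia list had a median of -0.18 (adjusted p = 3.5e-09; adjusted p = 0.917 with an estimated correlation), with 0 members up and 7 down adjusted over the list alone. That median shrank to -0.09 with the term (adjusted p = 1.93e-06; adjusted p = 0.836 with an estimated correlation), to -0.02 without the libraries that stand apart (adjusted p = 0.21) and to -0.09 without control 06 alone. Limma called 0 genes up and 6 down (4522 at an unadjusted p under 0.05), edgeR 0 and 5, DESeq2 9 and 21. With the term limma called 0 (1302 at an unadjusted p under 0.05; edgeR and DESeq2 were not run with it), while the fold changes stayed near their size: Fcrls -0.44 ± 0.09, Gpr34 -0.55 ± 0.12, P2ry12 -0.38 ± 0.09, Myo18b -0.65, Upk1b -0.92 and Cd209a -2.21, each at an adjusted p of 0.142. Without the libraries that stand apart 1 gene was called, which rose. With 1 library left out the count ran from 0, without any of 7 of the 12 libraries, to 31, without control 03.

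In MIA females the hippocampus gave Myo18b alone, lower in all 6 PLX libraries (44.0 to 58.4) than in all 7 controls (71.8 to 92.4; log2 fold change -0.68 ± 0.12, adjusted p = 0.0178). P2ry12 differed by -0.26 ± 0.08 (adjusted p = 0.357), Cx3cr1 by -0.21, Csf1r by -0.06 and Tmem119 by -0.03. Clock genes had a higher list median (0.13, adjusted p = 0.00045; adjusted p = 0.167 with an estimated correlation; 5 up and 1 down adjusted over the list alone). Immediate early genes, which neurons switch on with activity, had a lower one (-0.35, adjusted p = 4.04e-10; adjusted p = 0.482 with an estimated correlation; 1 down adjusted over the list alone), as did cholesterol synthesis (-0.15, adjusted p = 3.64e-09; adjusted p = 0.167 with an estimated correlation; 3 down). The unadjusted count was 1538 genes; edgeR called 1 gene, also lower, and DESeq2 2 up and 5 down. With the term 1 gene was called in each direction, and without the libraries that stand apart 1 rose. With 1 library left out the count ran from 0, without any of 7 libraries, to 5.

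In saline males the largest hippocampal change was in Hcar2, the niacin and ketone-body receptor of myeloid cells. Its signal was 8.91 to 17.6 in the 6 PLX libraries and averaged 1.46 ± 1.68 (SD) in the 6 controls (log2 fold change 2.85 ± 0.43, adjusted p = 0.000879). Derl3, which acts in the disposal of misfolded proteins, rose as well (1.45 ± 0.25, adjusted p = 0.00587; 31.6 to 77.9 against 13.2 to 29.5). Myo18b (-0.66, adjusted p = 0.02), Upk1b (-0.99, adjusted p = 0.0261) and Cd163, the haemoglobin scavenger receptor of macrophages at the brain's borders (-1.57 ± 0.31, adjusted p = 0.0261), fell. P2ry12 differed by -0.20 ± 0.08 (adjusted p = 0.198), Csf1r by -0.13 (adjusted p = 0.273), Tmem119 by -0.11 and Cx3cr1 by -0.07. Limma called 2 genes up and 3 down (4027 at an unadjusted p under 0.05), edgeR 2 and 3, DESeq2 2 and 8, and the fit with the term 2 and 2, with Upk1b at -0.93 ± 0.20 (adjusted p = 0.126). Without the libraries that stand apart limma called 0, from 2 control libraries, and with 1 library left out the count ran from 1 to 6.

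In MIA males the hippocampus again gave Myo18b alone (-0.73 ± 0.13, adjusted p = 0.0226), with at most 53.5 in the 6 PLX libraries and at least 62.5 in the 5 controls. P2ry12 differed by -0.22 ± 0.09 (adjusted p = 0.114), Tmem119 by -0.19, Cx3cr1 by -0.17 and Csf1r by -0.11. Ribosomal protein genes (median -0.27, adjusted p = 3.12e-10; adjusted p = 0.936 with an estimated correlation; 21 down adjusted over the list alone) and oxidative phosphorylation genes (-0.33, adjusted p = 4.17e-14; adjusted p = 0.936 with an estimated correlation; 35 down) were lower, as in the libraries that do not stand apart. At an unadjusted p under 0.05 there were 5632 genes; edgeR called 1 and DESeq2 3, all lower, the fit with the term 1, and limma without the libraries that stand apart 0. With 1 library left out the count ran from 0 to 3632, the highest without control 02.

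Prefrontal cortex of saline females lost the same kind of transcripts under the inhibitor. Upk1b (-1.67 ± 0.28, adjusted p = 0.00476) lay at 10.2 ± 5.66 (SD) in PLX libraries and 24.5 to 41.1 in controls. Fcrls (-0.57, adjusted p = 0.00476), Gpr34 (-0.58, adjusted p = 0.025), the sialic acid lectin Siglech of microglia (-0.46, adjusted p = 0.025) and Myo18b (-0.58, adjusted p = 0.0498) also fell. P2ry12 (-0.41 ± 0.10, adjusted p = 0.257), Cx3cr1 (-0.36), Tmem119 (-0.27) and Csf1r (-0.23 ± 0.06, adjusted p = 0.273) were not called. The microglia list had a median of -0.18 (adjusted p = 2.5e-12; adjusted p = 0.658 with an estimated correlation) and 15 members down adjusted over the list alone. That median was -0.12 with the term (adjusted p = 1.74e-12; adjusted p = 0.184 with an estimated correlation) and -0.04 without the libraries that stand apart (adjusted p = 0.0773). At an unadjusted p under 0.05 limma gave 3524 genes; edgeR called 0 up and 5 down, DESeq2 1 and 7. The fit with the term called 3, which were Upk1b, Fcrls and Myo18b, with Gpr34 at -0.50 ± 0.11 and Siglech at -0.39 ± 0.09 (adjusted p = 0.138 each), and the fit without the libraries that stand apart 1, which rose. With 1 library left out the count ran from 1 to 6.

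MIA females changed in both directions in prefrontal cortex. Fcrls (-0.58 ± 0.09, adjusted p = 0.00343) ran from 403 to 551 in PLX libraries and 557 to 812 in controls. Sdr42e1, a dehydrogenase/reductase (-0.39, adjusted p = 0.00483), and Myo18b (-0.57, adjusted p = 0.038) fell too. Hcar2 (2.23 ± 0.41, adjusted p = 0.0157; 3.04 to 16.7 against 0 to 2.98) and Ly9, a receptor of the SLAM family on immune cells (1.58 ± 0.31, adjusted p = 0.038), rose. P2ry12 differed by -0.34 ± 0.10 (adjusted p = 0.322), Cx3cr1 by -0.33, Csf1r by -0.19 and Tmem119 by 0.03. Clock genes had a higher median (0.16, adjusted p = 2.77e-06, and 0.0791 with an estimated correlation). Per2 (0.76 ± 0.19), Tef (0.23), Bhlhe41 (0.36) and Dbp (0.54) were among 6 members up adjusted over the list alone. Genes of striatal projection neurons, a neighbouring tissue, had a higher median in this comparison too. Limma called 2 up and 3 down (1505 at an unadjusted p under 0.05), edgeR 3 and 3, DESeq2 7 and 12; with the term limma called 9 and 8, and without the libraries that stand apart 0 and 4. With 1 library left out the count ran from 2 to 16.

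In the fit as designed, saline males gave the longest list of any comparison of 2 groups, in prefrontal cortex. With the term MIA females gave more there (17 genes against 14), and with array weights MIA males gave more in both tissues. Hcar2 rose from 0 to 1.01 in controls to 9.47 to 21.3 in PLX libraries (3.61 ± 0.43, adjusted p = 1.77e-06). Also higher were lysozyme Lyz2 (0.93 ± 0.17, adjusted p = 0.00453; 228 to 390 against 123 to 204), the endosomal sensor Tlr13 (0.67), the complement fragment receptor C3ar1 (0.62) and cathepsin C, Ctsc (0.42, adjusted p = 0.0215). The linker histone H1f4 (1.28), Pdk3, Gabpa, Tbc1d8b and Zfp72 complete the 10 smallest p-values upwards. Downwards these were Myo18b (-0.74 ± 0.12, adjusted p = 0.00163), Upk1b (-1.70), the chromatin assembly factor Chaf1a (-0.65 ± 0.11, adjusted p = 0.00392; 72.0 to 99.9 against 109 to 166), Fcrls (-0.55), the crystallin Crybb1 of microglia (-0.95), Cox18, Pdss2, Cd163 (-0.85), Sag and Zfp414. Csf1r differed by -0.21 ± 0.06 (adjusted p = 0.0713), P2ry12 by -0.21, Tmem119 by -0.17 and Cx3cr1 by -0.15. Limma called 45 genes up and 22 down (5506 at an unadjusted p under 0.05), edgeR 47 and 24, and DESeq2 629 and 607; with 1 library left out the count ran from 6 (without PLX 04) to 3818 (without control 06). With the term 9 and 5 were called, 12 of them shared with the first count; Tlr13 (0.60 ± 0.13, adjusted p = 0.0561), C3ar1 (0.57 ± 0.13, adjusted p = 0.0695) and Crybb1 (-0.80 ± 0.19, adjusted p = 0.089) no longer passed, with fold changes near those without the term. Without the libraries that stand apart 58 and 8 were called, 19 shared, with controls 02 and 06 as the only controls left.

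In prefrontal cortex of MIA males Hcar2 (2.63 ± 0.45, adjusted p = 0.00933; 1.05 to 16.1 against 0 to 0.980) and Ly9 (1.86 ± 0.34, adjusted p = 0.0104; 22.4 ± 3.81 against 5.48 ± 1.30 (SD)) rose. Upk1b (-1.67 ± 0.29, adjusted p = 0.00933) and Fcrls (-0.56 ± 0.10, adjusted p = 0.0102; 370 to 419 against 499 to 690) fell. P2ry12 (-0.35 ± 0.10, adjusted p = 0.141), Tmem119 (-0.23), Csf1r (-0.17) and Cx3cr1 (-0.16) were not called. The microglia list median was -0.13 (adjusted p = 0.0014; adjusted p = 0.655 with an estimated correlation), with 1 member up and 9 down adjusted over the list alone; it shrank to -0.04 with the term (adjusted p = 0.306) and -0.03 without the libraries that stand apart (adjusted p = 0.149). In the fit with the term, genes of activated microglia had a median of 0.15 (adjusted p = 6.16e-08, and 0.00251 with an estimated correlation). Complement genes had a median of 0.17 in that fit (adjusted p = 1.3e-05, and 0.0222 with an estimated correlation). Without the term 0 of 37 lists passed with an estimated correlation, and 1 list was higher at the preset correlation. Limma called 2 up and 2 down (4934 at an unadjusted p under 0.05), edgeR 2 and 3, DESeq2 1 and 1, the fit with the term 3 and 1 (Fcrls -0.44 ± 0.09, adjusted p = 0.0945), and the fit without the libraries that stand apart 0. With 1 library left out the count ran from 2 to 2000, the highest without control 05.

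Csf1r, the target of the inhibitor, was also compared alone in exact two-sided permutation tests (8 tests). By exact permutation in prefrontal cortex it was lower in MIA females (-0.19, p = 0.00233, adjusted p = 0.0173), saline males (-0.21, p = 0.00433, adjusted p = 0.0173) and MIA males (-0.17, p = 0.0130, adjusted p = 0.0346), while in saline females the difference of -0.23 gave p = 0.0563 (adjusted p = 0.0970). Its signal there was 2233 ± 108 against 2544 ± 108 in MIA females (mean ± SD). In hippocampus the exact permutation p ran from 0.0606 to 0.272. The mean of the microglia list gave exact p of 0.0216 to 0.481 over the 8 comparisons, with adjusted p of 0.104 or more.

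Averaging the inhibitor's effect over both sexes and prenatal treatments, with the term for the libraries that stand apart, gave genes in both directions. In hippocampus Hcar2 (1.99, adjusted p = 1.75e-06), Ly9 (1.32, adjusted p = 1.52e-05), the leukocyte surface protein Cd52 (0.85, adjusted p = 0.00235) and the integrin Itgax of CD11c-positive cells (0.73, adjusted p = 0.0237) rose. Denn2b, Cdh24, Ubr2, the helicase Recql4, the histone H3c15 and Clmn rose with them. Myo18b (-0.68 ± 0.06 without the term; adjusted p = 2.51e-08 with it), Cd163 (-1.45, adjusted p = 5.49e-07), Fcrls (-0.37, adjusted p = 1.22e-05), Upk1b, Cd209a, Mdfi, Abcg3, P2ry12 (-0.24, adjusted p = 0.0106), Cwc27 and Trnau1ap fell. Cx3cr1 fell too (-0.21, adjusted p = 0.0395), while Csf1r (-0.09, adjusted p = 0.242) and Tmem119 (-0.04, adjusted p = 0.785) were not called.

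Prefrontal cortex gave many of the same genes in the averaged comparison with the term. Hcar2 (adjusted p = 2.78e-09), Lyz2 (0.73, adjusted p = 5.52e-08), Ly9 (1.63, adjusted p = 6.08e-08), Cd52 (0.82, adjusted p = 8.31e-06), the Fc receptor Fcgr4, Itgax (1.08, adjusted p = 0.00104), complement C1qa (0.26, adjusted p = 0.00196), Derl3, the beta-glucan receptor Clec7a (1.06, adjusted p = 0.00262) and sialoadhesin Siglec1 (0.86, adjusted p = 0.00269) rose. Fcrls (-0.47, adjusted p = 4.45e-09), Myo18b, Upk1b, Cd163 (-0.72, adjusted p = 1.12e-06), Crybb1, P2ry12 (adjusted p = 0.00172), Cd209a, Siglech (adjusted p = 0.00213), Cx3cr1 (adjusted p = 0.00262) and the lectin Cd209b fell, and Csf1r fell as well (-0.19, adjusted p = 0.00278). Tmem119, another marker of resting microglia, was not called (-0.06, adjusted p = 0.674). Genes of activated microglia passed as a list (median 0.10, adjusted p = 1.57e-07, and 0.00544 with an estimated correlation; 9 up and 0 down adjusted over the list alone), as did complement genes (0.05, adjusted p = 1.96e-05, and 0.0371 with an estimated correlation; 7 up and 0 down). Without the term 0 of 37 lists passed with an estimated correlation in prefrontal cortex. In hippocampus activated microglia and complement genes did not hold with an estimated correlation in the fit with the term. Activated microglia gave an adjusted p = 0.0683 at the preset correlation and adjusted p = 0.545 with an estimated one, and complement adjusted p = 0.0126 and adjusted p = 0.536.

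The count of genes in the averaged inhibitor comparison changed with the handling of the libraries that stand apart. Without the term limma called 4142 genes up and 3830 down in hippocampus (9705 at an unadjusted p under 0.05; edgeR 3894 and 3997; DESeq2 4049 and 4027). In prefrontal cortex it called 3909 and 3590 (9329 at an unadjusted p under 0.05; edgeR 3642 and 3783; DESeq2 3796 and 3832). With the term 52 rose and 23 fell in hippocampus (70 shared with the count without it), and 23 rose and 20 fell in prefrontal cortex (40 shared). Without the libraries that stand apart 4 rose and 5 fell in hippocampus (9 shared) and 13 rose and 15 fell in prefrontal cortex (25 shared).

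**Figure D2:**
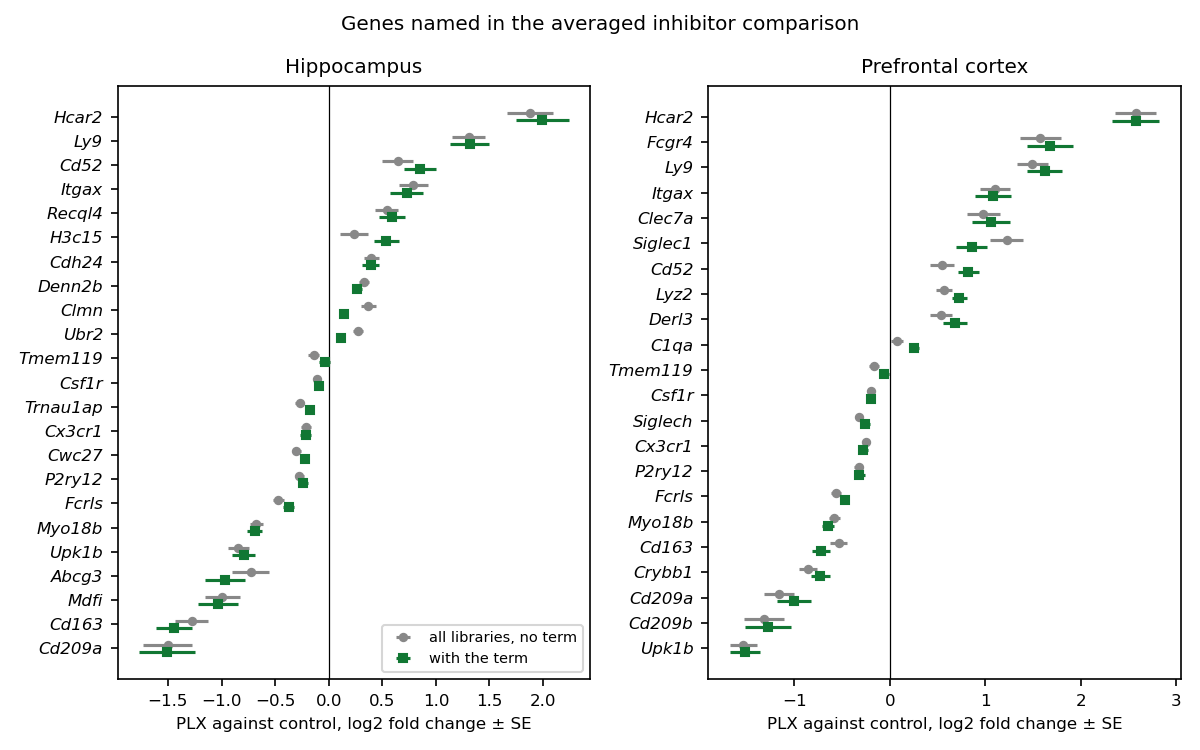
Log2 fold change (x axis, ± SE) of PLX against control averaged over sex and prenatal treatment for the named genes (y axis), without (grey circles) and with (green squares) a term for the libraries that stand apart. Hcar2 lies highest and Cd209a (hippocampus) or Upk1b (prefrontal cortex) lowest in each fit, while Csf1r differed by -0.09 and -0.19 with the term.

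Members of the microglia list moved apart in the averaged comparison with the term. Adjusted over the list alone, 7 members rose and 11 fell in hippocampus and 6 rose and 12 fell in prefrontal cortex. In both tissues C1qa (0.21 and 0.26), C1qb (0.20 and 0.18), C1qc (0.15 and 0.19), the protease Ctss (0.27 and 0.24) and Olfml3 (0.13 and 0.17) rose; without the term they differed by 0.04 and 0.08, 0.01 and -0.02, 0.04 and 0.05, 0.12 and 0.11, and 0.04 and 0.10. Adjusted over all genes only C1qa and Ctss of these passed with the term. Crybb1 (-0.47 and -0.73), Fcrls (-0.37 and -0.47), P2ry12 (-0.24 and -0.32), Gpr34 (-0.25 and -0.29), Cx3cr1 (-0.21 and -0.28), Siglech (-0.17 and -0.26), the transcription factor Spi1 (-0.22 in each) and Csf1r (-0.09 and -0.19) fell. The list median without the term was -0.10 in hippocampus (adjusted p = 0.00118; adjusted p = 0.855 with an estimated correlation) and -0.12 in prefrontal cortex (adjusted p = 8.04e-06; adjusted p = 0.792 with an estimated correlation), and with it -0.02 (adjusted p = 0.286) and -0.05 (adjusted p = 0.000665; adjusted p = 0.681 with an estimated correlation).

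**Figure D3:**
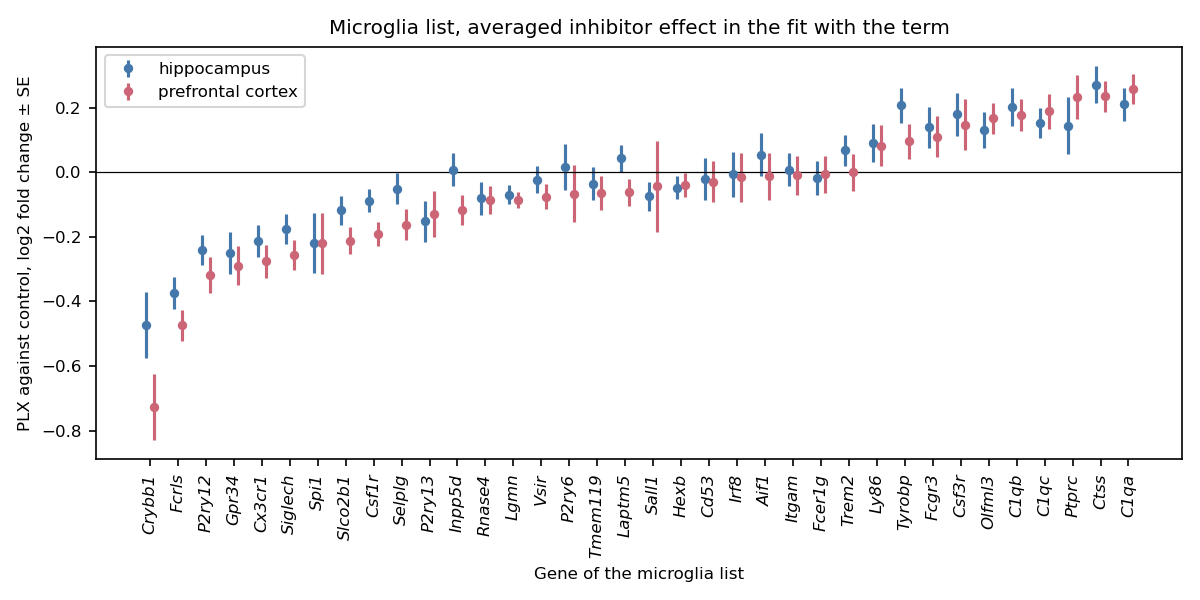
Log2 fold change of PLX against control (y axis, ± SE, with the term for the libraries that stand apart) for the 36 members of the microglia list (x axis) in hippocampus (blue) and prefrontal cortex (red), averaged over sex and prenatal treatment. C1qa, C1qb, C1qc, Ctss and Olfml3 lie above 0 and Crybb1 and Fcrls lie lowest in both tissues.

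Other gene groups also differed in the averaged inhibitor comparison without the term. Ribosomal protein genes (-0.19 in hippocampus, -0.25 in prefrontal cortex) and oxidative phosphorylation genes (-0.25 and -0.25) had lower medians, with 36 and 40 ribosomal and 37 and 37 oxidative members called down. Glutamate synapse genes (0.11 and 0.12) and perineuronal net genes (0.15 and 0.15) had higher medians, cholesterol synthesis lower ones (-0.12 and -0.11), and immediate early genes a lower one in hippocampus (-0.22, adjusted p = 0.00164). Every one of these lists stood at adjusted p = 0.855 with an estimated correlation in hippocampus and, immediate early genes aside, adjusted p = 0.792 with an estimated correlation in prefrontal cortex. With the term the medians shrank to -0.05 and -0.08 for ribosomal protein genes, -0.06 and -0.07 for oxidative phosphorylation, 0.01 and 0.01 for the glutamate synapse and 0.04 and 0.04 for perineuronal nets. They moved less for cholesterol synthesis (-0.08 and -0.08) and for immediate early genes in hippocampus (-0.17, adjusted p = 2.42e-05; adjusted p = 0.545 with an estimated correlation). Border macrophage genes moved both ways in prefrontal cortex, with Cd163 and Cd209f (-1.08 ± 0.16) lower and F13a1 (0.47 ± 0.09) and Folr2 (0.77 ± 0.19) higher; their list gave an adjusted p of 0.126 in hippocampus and 0.777 in prefrontal cortex. With the term, heat shock and endoplasmic reticulum stress genes had medians of 0.14 (adjusted p = 2.22e-07; adjusted p = 0.536 with an estimated correlation) and 0.17 (adjusted p = 3.4e-08; adjusted p = 0.388 with an estimated correlation). The remaining lists of cell types and processes did not pass without the term, at adjusted p of 0.112 to 0.989 in hippocampus and 0.108 to 0.812 in prefrontal cortex.

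Across genes, the inhibitor's effects in females and males went together with r of 0.685 in hippocampus and 0.673 in prefrontal cortex, and genes are not independent replicates. With the term these fell to 0.339 and 0.295, and without the libraries that stand apart to 0.158 and 0.134. No gene was called by limma, edgeR or DESeq2 for a sex difference in the response to the inhibitor; with array weights limma called 2282 in prefrontal cortex. The smallest p-values belonged to the growth factor Bdnf (-0.27 ± 0.07), Cop1 (-0.22) and Tulp3 (0.21) in hippocampus (adjusted p = 0.857 each) and to Tlr13 (-0.53 ± 0.13), the predicted Gm22175 (1.14) and the actin bundler Lcp1 (-0.33 ± 0.08) in prefrontal cortex (adjusted p = 0.823 each). At an unadjusted p under 0.05 limma gave 984 genes in hippocampus and 900 in prefrontal cortex, 4.94% and 4.54% of those tested. Chance alone would give a share of about 0.05.

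Maternal immune activation without the inhibitor went with higher immediate early genes in females. In prefrontal cortex 19 members of that list were higher and 0 lower adjusted over the list alone, led by the AP-1 subunits Fosb (1.00 ± 0.23) and Fosl2 (0.85 ± 0.20), the orphan receptor Nr4a3 (1.01 ± 0.26) and Klf2 (0.76 ± 0.20). The list median was 0.59 (adjusted p = 1.21e-25; adjusted p = 0.0657 with an estimated correlation). In hippocampus it was 0.45 (adjusted p = 9.74e-18; adjusted p = 0.139 with an estimated correlation), with 16 members up and 0 down adjusted over the list alone, among them Fosb (1.05 ± 0.23), Egr3 (0.30), Bdnf (0.25) and Nr4a3 (0.48). The mean of the list per library, tested by exact permutation (8 tests), was 10.14 ± 0.30 in 7 MIA and 9.59 ± 0.16 in 6 saline females in prefrontal cortex (difference 0.56, p = 0.0035, adjusted p = 0.0280). In hippocampus the same permutation test gave 9.66 ± 0.49 and 9.18 ± 0.24 (p = 0.0571, adjusted p = 0.163). Over the 48 labels the list mean in hippocampus and prefrontal cortex correlated (r = 0.779, rho = 0.758, permutation p = 1e-05 each, the smallest that 100000 permutations can give; r = 0.741 without the 2 farthest labels). After subtraction of group means r was 0.705 (permutation p = 1e-05) and rho 0.601 (p = 2e-05), with r = 0.688 without the 2 farthest labels.

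**Figure D4:**
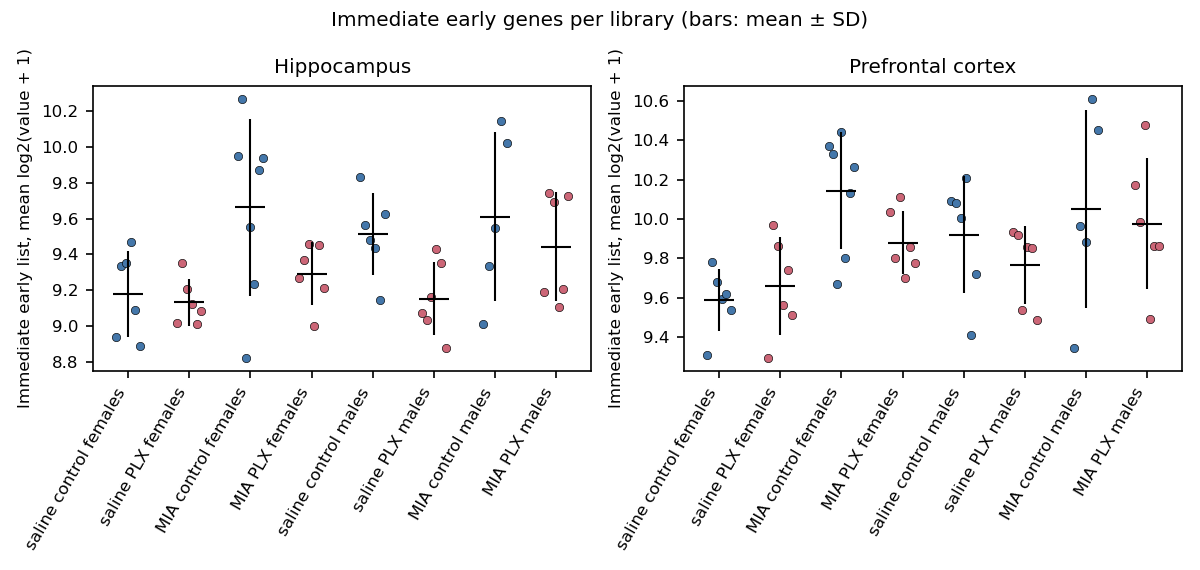
Mean of the immediate early list per library (y axis, log2(signal + 1)) in the 8 groups of each tissue (x axis); points are libraries, and bars mark mean ± SD. In females without inhibitor in prefrontal cortex the 7 MIA libraries average 10.14 and the 6 saline libraries 9.59.

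Genes of cholesterol synthesis were higher with them in females. In hippocampus Hmgcs1, the enzyme that feeds the mevalonate pathway, was 5878 to 8100 in the 7 MIA libraries and 4556 to 5840 in the 6 saline ones (0.35 ± 0.07, adjusted p = 0.000295 over the list alone). Cyp51 (0.32 ± 0.07) and Msmo1 (0.35) were among the 7 members up and 0 down adjusted over the list alone, and the median was 0.16 (adjusted p = 4.91e-11; adjusted p = 0.139 with an estimated correlation). In prefrontal cortex the median was 0.11 (adjusted p = 6.05e-06; adjusted p = 0.543 with an estimated correlation; 1 up adjusted over the list alone). Glucocorticoid response genes had medians of 0.12 in hippocampus (adjusted p = 0.00484; adjusted p = 0.818 with an estimated correlation; 5 up) and 0.13 in prefrontal cortex (adjusted p = 0.000443; adjusted p = 0.716 with an estimated correlation; 5 up). Pdk4, which restrains glucose oxidation, was 280 to 450 in MIA and 210 to 255 in saline females in prefrontal cortex (0.51 ± 0.11) and differed by 0.58 ± 0.13 in hippocampus; Cdkn1a and Arl4d also belong to these members. Of the clock genes Arntl was higher (0.37 in hippocampus, 0.35 in prefrontal cortex) and Dbp (-0.66 and -0.53) and Bhlhe41 (-0.29 and -0.39) lower. The clock list had medians of -0.15 in each tissue (adjusted p = 0.0088 and 0.000443; adjusted p = 0.338 with an estimated correlation in hippocampus and adjusted p = 0.304 with an estimated correlation in prefrontal cortex). The microglia list was lower in hippocampus (-0.13, adjusted p = 1.05e-06; adjusted p = 0.795 with an estimated correlation; 1 down; -0.08 with the term). Saline controls 05 and 06 had the highest means of that list there (8.81 and 9.09). The other saline females lay at 8.46 to 8.69 and the MIA females at 8.41 to 8.76, so the lower median leans on these saline libraries.

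Over all genes the predicted gene Gm13502 alone was called after MIA in females, in hippocampus (0.59 ± 0.11, adjusted p = 0.0278). With 1 of its 13 libraries left out the count in hippocampus ran from 0 to 5. Limma gave 1278 genes at an unadjusted p under 0.05 there, edgeR called 1 gene up and DESeq2 11 up and 4 down. With the term 8 rose and 2 fell, among them Hmgcs1 (0.38, adjusted p = 0.015), Cyp51 (0.34, adjusted p = 0.0175), Fosb (1.07, adjusted p = 0.0497) and Pdk4 (0.61, adjusted p = 0.0376); without the libraries that stand apart 0 were called. In prefrontal cortex limma called 0 genes (992 at an unadjusted p under 0.05), edgeR 0 and DESeq2 2 up; the smallest p-values were those of Pdk4 (adjusted p = 0.325), Fosb (adjusted p = 0.473), Gm42849 (-0.78), Fosl2 (adjusted p = 0.473) and Gm3764 (-0.63).

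In males MIA without the inhibitor went with lower glucocorticoid response genes. Medians were -0.26 in hippocampus (adjusted p = 7.92e-13; adjusted p = 0.219 with an estimated correlation; 1 down adjusted over the list alone) and -0.26 in prefrontal cortex (adjusted p = 5.53e-10; adjusted p = 0.643 with an estimated correlation). The sulfotransferase Sult1a1 (-0.74 ± 0.22 and -0.59 ± 0.21) and the lipid droplet protein Plin4 (-1.43 ± 0.57 and -1.73 ± 0.67) led. Immediate early genes had medians of 0.07 (adjusted p = 0.0164; adjusted p = 0.726 with an estimated correlation) and 0.10 (adjusted p = 0.0325; adjusted p = 0.971 with an estimated correlation). The genes with the smallest p-values were the small nucleolar RNA Snord72 (-1.57 ± 0.32, adjusted p = 0.312), Gm15892, Gm37353, Adamtsl5 (0.58) and Dmgdh (0.98) in hippocampus, and Sag (-0.46), Naip1 (-1.14), Mapk15 (-1.32), Gm6568 and Xkrx (0.63) in prefrontal cortex (adjusted p = 1). Limma, edgeR and DESeq2 each called 0 (limma 475 and 508 at an unadjusted p under 0.05).

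The MIA effect without inhibitor differed between the sexes for lists at the preset correlation only, not for single genes. Glucocorticoid response genes were higher in females than males in that difference, with medians of 0.45 in each tissue (adjusted p = 5.38e-13 and 6.91e-17; adjusted p = 0.208 with an estimated correlation in hippocampus and adjusted p = 0.0931 with an estimated correlation in prefrontal cortex). Adjusted over the list alone, 4 members were up in hippocampus, led by Pdk4 (0.71 ± 0.19), Errfi1 (0.47), Cdkn1a (1.23 ± 0.36) and Arl4d (0.83), and 5 in prefrontal cortex. Immediate early genes had medians of 0.35 and 0.41 (adjusted p = 4.6e-06 and 1.51e-10; adjusted p = 0.998 with an estimated correlation and adjusted p = 0.75 with an estimated correlation). Limma, edgeR and DESeq2 called 0 genes (limma 732 in hippocampus and 404 in prefrontal cortex at an unadjusted p under 0.05). The smallest p-values were those of 4930588G17Rik, Zfp493 (0.58) and Tob2 (0.48) in hippocampus and Gm13420, Pdk4 (0.64 ± 0.16) and Gm20083 in prefrontal cortex. Across genes the MIA effects in females and males had r of 0.039 in hippocampus and 0.155 in prefrontal cortex.

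With the inhibitor, immediate early genes had higher medians after MIA than after saline in both sexes. In females these were 0.11 in hippocampus (adjusted p = 0.00516; adjusted p = 0.899 with an estimated correlation) and 0.20 in prefrontal cortex (adjusted p = 0.000116; adjusted p = 0.741 with an estimated correlation). In males they were 0.17 (adjusted p = 8.13e-06; adjusted p = 0.772 with an estimated correlation) and 0.17 (adjusted p = 0.000677; adjusted p = 0.668 with an estimated correlation). The list mean gave exact permutation p of 0.102 and 0.0952 in females and 0.0823 and 0.214 in males (differences of 0.16, 0.22, 0.29 and 0.21). In these females markers of neighbouring tissue moved as well, striatal genes up in prefrontal cortex and choroid plexus genes down in hippocampus. MIA males had lower heat shock genes than saline males under the inhibitor (-0.16 in hippocampus, adjusted p = 2.21e-09; adjusted p = 0.772 with an estimated correlation; -0.16 in prefrontal cortex, adjusted p = 1.82e-05; adjusted p = 0.668 with an estimated correlation). No gene was called by limma, edgeR or DESeq2 in these 4 comparisons. In females limma gave 546 genes in hippocampus and 1062 in prefrontal cortex at an unadjusted p under 0.05, and in males 493 and 573. The smallest p-values in females belonged to 4930588G17Rik (-1.14), Mthfs (0.58), Gm24166, Gm36388 and Gm6736 in hippocampus and to Dapp1 (0.37), the interleukin receptor Il17re (-0.93), Wnt10a (0.67), Zfp493 (-0.33) and Gm49708 in prefrontal cortex. In males these were Gm18406, Gm13054, Mir541 (1.18), Gm17111 and Gm5492 in hippocampus and Chaf1a (0.44 ± 0.11), Rps2-ps13, CK137956, Gm11408 and Gm17149 in prefrontal cortex.

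For the interaction of MIA with the inhibitor some lists passed camera at its preset correlation, and 0 of those tested in either tissue passed with an estimated one. In females immediate early genes (-0.30 in hippocampus, adjusted p = 4.46e-05; adjusted p = 0.751 with an estimated correlation; -0.31 in prefrontal cortex, adjusted p = 0.000111; adjusted p = 0.772 with an estimated correlation) had negative medians and microglia genes positive ones (0.18, adjusted p = 2.19e-06; adjusted p = 0.751 with an estimated correlation; 0.14, adjusted p = 5.05e-05; adjusted p = 0.772 with an estimated correlation). The microglia medians lean on saline control females 05 and 06, with list means of 8.81 and 9.09 in hippocampus and 8.96 and 8.98 in prefrontal cortex. The other saline control females lay at 8.46 to 8.69 and 8.39 to 8.59. Single genes with the smallest p-values were Gm6736 (0.83 ± 0.17, adjusted p = 0.27), Gm17597 and Klhdc1 (-0.29) in hippocampus and Zfp493 (-0.54), Ckap2l (-1.18) and Mir6955 in prefrontal cortex. In males they were Dmgdh (-1.43), Mms22l (0.70) and Snord72 (1.68), and in prefrontal cortex Chaf1a (0.70 ± 0.16), 1700112D23Rik and Ogdhl (0.32). For the difference of the interaction between sexes they were Mms22l (-1.13), Ky (-1.12) and Gm36388, and in prefrontal cortex Tent5c (0.80), Chaf1a (-0.85) and Spag6 (-0.83). Limma, edgeR and DESeq2 called 0 genes in each of these 6 tests; at an unadjusted p under 0.05 limma gave 570, 425 and 517 in hippocampus (females, males, difference) and 612, 797 and 492 in prefrontal cortex.

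Averaged over sex and inhibitor, genes of cholesterol synthesis were higher after MIA in hippocampus. The list median was 0.07 (adjusted p = 1.05e-14, and 0.0443 with an estimated correlation), with 8 members up and 0 down adjusted over the list alone, among them Cyp51 (0.17 ± 0.04), Hmgcs1 (0.14) and Idi1 (0.21). With the term for the libraries that stand apart 11 members were up, at adjusted p = 0.0515 with an estimated correlation. Immediate early genes had medians of 0.20 in hippocampus (adjusted p = 1.51e-22; adjusted p = 0.0533 with an estimated correlation) and 0.25 in prefrontal cortex (adjusted p = 1.94e-22; adjusted p = 0.12 with an estimated correlation), with 14 members up and 0 down adjusted over the list alone in each tissue. Oligodendrocyte genes had medians of 0.12 (adjusted p = 1.8e-07; adjusted p = 0.543 with an estimated correlation) and 0.08 (adjusted p = 8.98e-07; adjusted p = 0.496 with an estimated correlation). Limma and edgeR called 0 genes in both tissues (limma 949 and 1183 at an unadjusted p under 0.05), and DESeq2 7 up and 3 down in hippocampus and 5 up in prefrontal cortex. With the term Cyp51 (0.18, adjusted p = 0.0364) and Gm13502 (0.27, adjusted p = 0.0364) were called in hippocampus, and the G protein regulator Rgs4 (0.14 ± 0.03, adjusted p = 0.0446), AC159819.1 and Gm21781 in prefrontal cortex. Without the libraries that stand apart limma called 0 in each tissue.

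Females and males differed, averaged over treatments, in genes beyond the sex chromosomes. Xist (10.82 ± 0.17 in hippocampus, 11.50 ± 0.19 in prefrontal cortex) and Ddx3y (-10.74 ± 0.09 and -10.83 ± 0.06) led, with Eif2s3x, Kdm6a, Kdm5c, Ddx3x and Pbdc1 higher in females in both tissues and Uty, Eif2s3y and Kdm5d higher in males. Among other genes, Fcrls was higher in females in both tissues (0.23 ± 0.05, adjusted p = 0.0283, and 0.25 ± 0.05, adjusted p = 0.00481). So were the X-linked Jpx, the retinol transporter Stra6 (0.41, adjusted p = 0.000589) and the metallothionein Mt2 (0.40, adjusted p = 0.02) in hippocampus, and Siglec1 (1.01 ± 0.17, adjusted p = 0.000469), Lars2 (0.54) and Rab10os in prefrontal cortex. Diaph1 (-0.11, adjusted p = 0.00767), Kifc2 (-0.15), the X-linked Igsf1 (-0.25) and the repressor Bcl6 (-0.17) were higher in males in hippocampus, and the Y-linked Uba1y in prefrontal cortex. With the term St6galnac6 and the X-linked Rtl3 joined them in hippocampus, and Eif4enif1, Hira, Cry2, Ccdc149 and Wdr48, whose differences were at most 0.14 in size, in prefrontal cortex. Genes of oligodendrocyte precursors were higher in females in prefrontal cortex (median 0.09, adjusted p = 5.67e-05, and 0.00793 with an estimated correlation; 3 up adjusted over the list alone: Neu4, Cspg4 and Pdgfra). Border macrophage genes were higher in female hippocampus (0.42, adjusted p = 1.24e-06, and 0.0914 with an estimated correlation). Lyve1 (0.56), Cd163 (0.52) and Clec10a (0.49) were up adjusted over the list alone. Choroid plexus list means ran from 4.87 to 10.42 over libraries there, so uneven dissection stays open. Limma called 35 genes up and 14 down in females in hippocampus (1566 at an unadjusted p under 0.05; edgeR 37 and 14; DESeq2 53 and 28) and 18 and 10 in prefrontal cortex (1200; edgeR 23 and 10; DESeq2 28 and 14). With the term the counts were 60 and 27 (49 shared) and 30 and 17 (28 shared), and without the libraries that stand apart 13 and 8 (20 shared) and 15 and 8 (20 shared).

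No gene was called for a tissue difference in the response to MIA or the inhibitor, in either sex. With the animal label as block the 12 named results stayed uncalled. The difference averaged over the sexes was not tested. The smallest p-values were those of Mir8094 (1.45 ± 0.38), Gm10941 and 5430402O13Rik for MIA in females, Aldh3a1 (0.97 ± 0.25), Gm29508 and the orexin receptor Hcrtr2 (-0.51 ± 0.14) for the inhibitor in females, Snord72 (-2.05), Slc23a3 (1.73) and Tafa1 (-0.38) for MIA in males, and Gabra3 (-0.26 ± 0.07), Ccn3 (-0.41) and Gm10638 for the inhibitor in males (adjusted p = 1 each). Limma and edgeR called 0 genes in each, with 258, 339, 348 and 336 by limma at an unadjusted p under 0.05. These counts lie below chance, so this fit without a block may miss differences.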

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

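Tests of the libraries that stand apart, of fewer microglia and of the inhibitor against the state of the libraries were chosen only after the results were seen. The tests of transcript length, blood leukocytes, clock genes, single libraries and other splits of the samples were planned. Those of transcript length and blood leukocytes, and some of the splits, concern averaged comparisons, which were themselves chosen after seeing the data. The criterion for the list differences below was also chosen after the data were seen, and a narrower one was tried and set aside.

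A library far from the others of its group was found 6 times in 80 tests of 5 measures (Dixon's test; chance alone gives such a library in about 1 of 20 groups per measure). Recovered reads were 25.006 M in MIA PLX male 01 in prefrontal cortex, with the nearest other library at 24.3434 M. The share of ribosomal protein and oxidative phosphorylation reads was 0.649% in MIA PLX female 06 (nearest 0.488%) and 0.620% in saline PLX male 05 (nearest 0.484%) in hippocampus. In prefrontal cortex it was 0.675% in MIA PLX female 06 (nearest 0.510%) and 0.597% in saline PLX male 05 (nearest 0.469%), and saline control male 06 was lowest at 0.428% (nearest 0.593%). The 4 high values belong to the only PLX libraries among those that stand apart.

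Gene lists differed between groups beyond the planned gene counts in 13 pairs of a list and a term that passed camera in both tissues in one direction, without and with the term for the libraries that stand apart. They come from 180 pairs, of which 56 passed in at least 1 tissue and 23 in both; with an estimated correlation 0 of the 180 passed in both tissues, and the narrower criterion would have left 1. In the sex difference of the MIA effect without inhibitor, medians in hippocampus and prefrontal cortex were 0.45 and 0.45 for glucocorticoid response genes, 0.35 and 0.41 for immediate early genes and 0.11 and 0.10 for cholesterol synthesis. In the sex difference of the inhibitor's effect they were 0.21 and 0.16 for glucocorticoid response, 0.09 and 0.12 for the clock and -0.16 and -0.15 for interferon response. The interaction of MIA with the inhibitor gave -0.30 and -0.31 for immediate early genes and 0.18 and 0.14 for microglia genes in females, and 0.25 and 0.21 for glucocorticoid response and -0.18 and -0.18 for heat shock in males. Its difference between the sexes gave -0.46 and -0.39 for glucocorticoid response, -0.28 and -0.41 for immediate early genes and 0.22 and 0.20 for microglia genes. These are hypotheses for other animals, since the same libraries suggested and tested them and the estimated correlation left adjusted p of 0.0931 or more. Both microglia terms include saline control females 05 and 06, whose list means were the highest in each tissue.

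The averaged inhibitor comparison called a large share of all genes tested, and most of that count may come from the uneven spread of 14 libraries over the groups. With a term for them 70 of the 7972 calls in hippocampus and 40 of the 7499 in prefrontal cortex remained, and the median of oxidative phosphorylation genes moved from -0.25 to -0.06 and -0.07. With a trend of transcript length and GC content removed, 5552 of 7828 and 4518 of 7357 calls of known length stayed. Longer genes were lower in the libraries that stand apart (rho = -0.441 and -0.476), which still parted, so a length-linked source stays open. Whether the inhibitor moves animals out of that state stays open, as the design gives no measure of it before treatment. It held 12 of 24 control and 2 of 24 PLX labels (exact p = 0.00335). The order of dissection, extraction and sequencing is not in the labels, so a batch could also be the source.

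Resting-microglia genes moved apart under the inhibitor, some up and some down. Fewer microglia with unchanged expression per cell would lower all of them. With the term, 7 of the list rose past the threshold in hippocampus and 6 in prefrontal cortex, adjusted over the list alone, while 11 and 12 fell. Without the libraries that stand apart 6 and 7 rose. In the fit without the term several of these members lay near 0 (Tyrobp 0.00, C1qb 0.01 and C1qa 0.04 in hippocampus, C1qb -0.02 and C1qa 0.08 in prefrontal cortex), so the rise depends on the handling of these libraries. A fall in number alone is argued against only under that handling. Fewer microglia that also changed their expression could give the same split, so a fall in number is not set aside. Uneven spread of the libraries that stand apart is not a full account, since without them 8 members were lower in hippocampus and 12 in prefrontal cortex. Entry of blood leukocytes would raise their markers. In prefrontal cortex the median of 5 markers was -0.24, with Trbc2 (-0.39), S100a9 (-0.38) and Cd4 (-0.24) lower and Mmp9 (0.20) and Ccr2 (0.10) higher. S100a9 and Ccr2 lay at mean signals of 7.07 and 11.3, and Cd4 at 111 there against 6.55 in hippocampus. In hippocampus the median was 0.15 over 3 markers with a standard error of 0.32. Cd52 and Ly9, also genes of immune cells, rose in both tissues, so these markers cannot decide on leukocytes in either tissue. A changed state of microglia, or a renewed population with another profile, may remain as an explanation, and bulk RNA does not part these.

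Immediate early genes were higher after MIA in females without the inhibitor. With a clock score as covariate the list median was 0.53 in hippocampus and 0.55 in prefrontal cortex, against 0.45 and 0.59 without it. In hippocampus the score itself ran from -0.94 to 0.19 in these MIA females and from -0.12 to 0.27 in the saline ones. The test speaks only to a shift that this score follows, and cannot decide on time of day or handling. No single library carried the higher list median, with lowest medians of 0.39 and 0.46 when each was left out. Nor did the libraries that stand apart (0.46 and 0.62 with the term, 0.34 and 0.39 without them). The list mean went together in both tissues of a label (r = 0.705 after group means were subtracted). A state of the animal at death, from arousal to handling, might therefore be seen rather than a lasting effect of MIA. Litter is not in the labels, so a difference between litters was not tested and stays open as well.

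Other splits of the same libraries into groups of the same sizes were fitted, 100 per comparison with the real one included. Each comparison was judged singly. In hippocampus 4 splits were as large as the real one for the inhibitor in saline females (6 genes; highest other split 1284) and in MIA females (1; highest other 30), a share just under 0.05; leaving out any of 7 libraries gave 0 calls in either, so chance is not firmly excluded there. In hippocampus fewer than 5 of 100 splits were as large for the inhibitor in saline males (5 genes, highest other 1, 1 split). The same held there for the averaged inhibitor comparison (7972, highest other 3, 1 split) and sex (49, highest other 1764, 2 splits). In prefrontal cortex it held for the inhibitor in saline females (5, highest other 1, 1 split) and MIA females (5, highest other 16, 2 splits). It also held there in saline males (67, highest other 7126, 3 splits) and MIA males (4, highest other 0, 1 split). The averaged inhibitor comparison (7499, highest other 4245, 1 split) and sex (28, highest other 1, 1 split) were further cases in prefrontal cortex. Such shares, judged singly, do not exclude chance. With only the compared groups in the fit, saline males in hippocampus and saline and MIA females in prefrontal cortex gave 0 genes. In hippocampus 5 or more splits were as large for MIA in females without inhibitor (1 gene, highest other 6138, 9 splits) and the inhibitor in MIA males (1, highest other 1, 5 splits). Comparisons with 0 genes called are matched by all 100 splits, with highest other counts from 0 to 7307. Splits that call many times the real count point to a structure of the samples. In every other split with over 100 genes the contrast of the shares of libraries that stand apart was at least 0.35 in size, yet the real split of saline females for the inhibitor in hippocampus had -0.50 with 6 genes, and over the comparisons the count and the size of this contrast had rho of -0.07 to 0.39. For the averaged inhibitor in prefrontal cortex the split with 4245 genes had a contrast of 0.42, near the -0.43 of the real split in size. Uneven spread of the libraries that stand apart is a candidate source and is not shown to be the whole one.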

How the results depend on the processing

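The term for the libraries that stand apart and the fit without them were chosen only after the result was seen; the other alternatives were planned. Of 246 named gene results, 206 kept their direction and side of the threshold with that term, 245 with edgeR and 246 with a pseudocount of 5. Of 242, 178 did so without the libraries that stand apart, and of 234, 205 did so with DESeq2. Of 132, 92 did so with only the compared groups in the fit, and 40 no longer passed. Results of comparisons with 0 calls count as kept when they stay uncalled, and the averaged comparisons name genes by the fit with the term. These shares therefore say little about how firm the called genes are. The cause was not tested for any change below, except that fewer libraries or genes were fitted where this is named. About 24 M reads per library leave genes under a signal of 10 untested or noisy; Hcar2, at 0 to 21.3 in prefrontal cortex, is among the lowest named. Counts are of genes called by limma unless another tool is named; counts of 0 have their unadjusted counts in the report.

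With the term, hippocampus gave 10 genes for MIA in inhibitor-free females, 0 for the inhibitor in saline females (1302 at an unadjusted p under 0.05) and 2 in MIA females, 75 for the averaged inhibitor, 2 for averaged MIA and 87 for sex. Prefrontal cortex gave 3 in saline females, 17 in MIA females, 14 in saline males, 43 for the averaged inhibitor, 3 for averaged MIA and 47 for sex. In hippocampus Tmem119 turned to 0.0034 in MIA females and 0.016 in saline males under the inhibitor, and the microglia list median to 0.037 in saline males and 0.019 in MIA males; in prefrontal cortex of MIA males it shrank to -0.036. Agreement across genes of the inhibitor's effects in saline and MIA males fell to 0.209 and 0.149 in hippocampus and prefrontal cortex, and that of females and males to 0.339 and 0.295.

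Without the libraries that stand apart, with fewer libraries, hippocampus gave 0 genes for MIA in females, 1 for the inhibitor in saline females, 0 in saline males and 0 in MIA males, 9 for the averaged inhibitor and 21 for sex. Prefrontal cortex gave 1 in saline females, 0 in MIA males and 28 averaged. The microglia median was -0.024 (saline females), 0.020 (saline males) and 0.0021 (MIA males) in hippocampus, and -0.041 (saline females) and -0.034 (MIA males) in prefrontal cortex. Tmem119 turned to 0.032 in saline males in hippocampus, and to -0.016 in MIA females and 0.0054 in saline males in prefrontal cortex. Agreement across genes between saline and MIA was 0.125 in females and 0.197 in males in hippocampus and -0.0954 in males in prefrontal cortex, a reversal. Between the sexes it was 0.158 and 0.134 for the inhibitor, and -0.172 for MIA in prefrontal cortex.

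DESeq2 called 15 genes for MIA in females in hippocampus, and 30, 7, 10 and 3 for the inhibitor in saline females, MIA females, saline males and MIA males, 10 for averaged MIA and 81 for sex. In prefrontal cortex it called 2 for MIA in females, 8, 19, 1236 and 2 for the inhibitor in the same order, and 5 for averaged MIA. Array weights, which give noisy libraries less weight, raised several counts into the 1000s. In hippocampus they gave 11 for MIA in females, 1 for MIA in males, 5513, 14, 6295 and 8951 for the inhibitor in that order, 22 for averaged MIA and 447 for sex. In prefrontal cortex they gave 14, 8284 and 8807 for the inhibitor in MIA females, saline males and MIA males, 2282 for the sex difference of the inhibitor's effect and 3215 for sex, with Wdr48 turning from -0.03 to 0.026.

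Only genes with a mean of at least 100, which tests fewer genes, gave 3, 0, 0 and 0 for the inhibitor in hippocampus in that order and 3, 2, 218 and 1 in prefrontal cortex. Without a filter MIA males in hippocampus gave 2, and the microglia list in saline males in prefrontal cortex passed camera at the same median of -0.107; with equal library totals it passed at -0.136. Dissection covariates gave 0 for MIA in females and 0 for the inhibitor in MIA males in hippocampus, where the microglia list passed at -0.095, and 3 in saline females, 136 in saline males and 3536 averaged in prefrontal cortex. With only the compared groups in the fit, and so fewer libraries, hippocampus gave 0 for MIA in females and 0, 0 and 0 for the inhibitor in saline females, MIA females and saline males; prefrontal cortex gave 0, 0, 4 and 1. With an estimated correlation the microglia list no longer passed in saline females (medians -0.181 in hippocampus, -0.183 in prefrontal cortex), nor in MIA females (-0.059) and MIA males (-0.133) in prefrontal cortex.

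The replicate number as a block gave 0 for MIA in females and 3, 0, 3 and 0 for the inhibitor in hippocampus in that order, with the microglia list at -0.049 in MIA females. In prefrontal cortex the block gave 2 in MIA females and 23 in saline males, and Tmem119 in MIA females turned to -0.013. The numbers do not pair libraries within a tissue (mean r of residuals 0.0063 in hippocampus and -0.0017 in prefrontal cortex over 161 pairs of a number), while the same label in both tissues gave a mean r of 0.285, a hint that a label is one animal.

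Leaving out 1 library changed counts from single groups. In hippocampus MIA in females gave 0 to 5 genes (5 without MIA control 03, 2 without MIA control 04 or saline control 02, and 0 without MIA control 01, 05 or 07 or saline control 03, 04, 05 or 06). The inhibitor gave 0 to 31 in saline females (31 without control 03, 22 without PLX 02, 10 without control 01, 3 without PLX 01, 1 without control 02, and 0 without any of the other 7), and 0 to 5 in MIA females (5 without control 05, and 0 without control 01, 02, 06 or 07 or PLX 01, 02 or 03). In saline males it gave 1 to 6, with 1 without PLX 06 and 2 or 3 without any other but control 06 or PLX 01. In MIA males it gave 0 to 3632 (3632 without control 02, 2928 without control 05, 2 without PLX 04, and 0 without control 03 or PLX 01, 03 or 05). Averaged MIA gave 0 to 2 (2 without MIA PLX female 04 or saline control female 02, 1 without MIA control male 05).

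In prefrontal cortex MIA in females gave 0 to 3 with 1 library left out (3 without MIA control 03). The inhibitor gave 1 to 6 in saline females (1 without PLX 05; 2 without control 04 or 05 or PLX 01, 02 or 06; 3 without control 06 or PLX 03). In MIA females it gave 2 to 16 (16 without PLX 03, 15 without control 05, 11 without PLX 01, 3 without control 01 or PLX 02 or 05, and 2 without control 06 or 07 or PLX 04). In saline males it gave 6 to 3818 (3818 without control 06, 2970 without PLX 05, 38 without PLX 03, 20 without PLX 01, 16 without control 02, 14 without PLX 06, 12 without control 05, 11 without PLX 02, 7 without control 01, 6 without PLX 04). In MIA males it gave 2 to 2000 (2000 without control 05, 1709 without control 02, 2 without control 03 or PLX 03). Tmem119 in MIA females ran from -0.0848 to 0.0421 in hippocampus and from -0.0503 to 0.0757 in prefrontal cortex. The microglia median ran from -0.0725 to 0.0156 (MIA females), -0.121 to -0.0380 (MIA males) and -0.0798 to -0.0101 (saline males) in hippocampus, and from -0.251 to -0.0877 (without control 06) in saline females there. In prefrontal cortex it ran from -0.245 to -0.129 (saline females), -0.0904 to -0.0444 (MIA females), -0.132 to -0.0837 (saline males) and -0.177 to -0.103 (MIA males).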

Other observations

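Tests that use the term for the libraries that stand apart or the averaged inhibitor comparison were chosen only after the result was seen. Heat shock and endoplasmic reticulum stress genes had a higher median in saline males under the inhibitor in hippocampus. In hippocampus the list median was 0.23 (adjusted p = 0.00326; adjusted p = 0.846 with an estimated correlation), with the co-chaperone Sdf2l1 (0.73 ± 0.27), the inducible chaperone Hspa1b (0.60 ± 0.22), Hyou1 (0.27) and Hsph1 (0.24) at the smallest p-values. With the term it was 0.33 (adjusted p = 5.45e-18; adjusted p = 0.199 with an estimated correlation; 16 up and 0 down adjusted over the list alone), and in prefrontal cortex 0.16 without the term, not past the threshold (adjusted p = 0.092; adjusted p = 0.86 with an estimated correlation) and 0.29 with it (adjusted p = 1.12e-09; adjusted p = 0.546 with an estimated correlation; 13 up and 0 down). Derl3, called in saline males in hippocampus, acts in the same pathway.

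Markers of neighbouring tissue varied between groups in prefrontal cortex. Genes of striatal projection neurons had medians of 0.76 for MIA against saline in PLX females (adjusted p = 4.3e-08; adjusted p = 0.741 with an estimated correlation), 0.51 for the inhibitor in MIA females (adjusted p = 3.75e-05; adjusted p = 0.71 with an estimated correlation) and -0.49 for the inhibitor in saline males (adjusted p = 0.0236; adjusted p = 0.86 with an estimated correlation), with 0 members past the threshold adjusted over the list alone in each. Choroid plexus genes in hippocampus had medians of -0.68 for the inhibitor in MIA females (adjusted p = 0.0164; adjusted p = 0.738 with an estimated correlation) and -0.64 for MIA in PLX females (adjusted p = 0.0383; adjusted p = 0.899 with an estimated correlation). In the averaged inhibitor comparison without the term, a T cell receptor transcript, Trbc2, differed by -0.39 ± 0.10 in prefrontal cortex (adjusted p = 0.00376) and Cd4 by -0.75 ± 0.18 in hippocampus (adjusted p = 0.00176), at mean signals of 123 and 6.55.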
